A study of Homo sapiens and Saccharomyces cerevisiae with 12 samples.

How the data were processed

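RNA of SG cores and total RNA was sequenced from U-2 OS cells and from yeast, with 3 libraries in each of 4 groups, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, ribosomal RNA was removed and DNA was digested before directional library kits were used, with 10 ng of depleted RNA per human library. The human cells were grown in 3 dishes of 500 cm2, and total RNA was taken from 5% of the lysate. The yeast cultures measured 2.4 L, and the series design describes 3 independent biological replicates per yeast group. Per the labels' protocols, yeast SG and total RNA came from the same culture, but nothing says that the replicate numbers mark it. Nothing says whether the U-2 OS libraries came from separate cultures, so the authors' p values for them may measure technical spread only. The submitters' processing notes name Trimmomatic 0.32, TopHat2, Bowtie2, HTSeq, Cuffdiff, Bowtie 0.12.7, DESeq 1.22.1 and the genome build R64, without saying which served which organism. The human genome build and the strand setting of the counting are not given in the sources used here.

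The yeast table held, per the file headers, a value for each library, the group means of the authors, their fold and p-value and their call. The deposited yeast signal values were whole read counts divided by 1 factor per library: 100% of values in each library came out whole within 0.01 reads when divided by the value of 1 read. Factors were between 0.728 and 1.25, and totals of recovered reads lay between 36500472 and 49568442 per library, so that counting error is small beside the spread between libraries for all but low genes. The table held 6575 yeast gene IDs, of which 5900 were in the R64 annotation used here, 5899 with a coding length. Those lengths were summed over coding sequence only, without untranslated regions, so the text gives coding length. All were multiples of 3. The human table held, per the file headers, 1 FPKM value per gene and group, and the log2 fold, p-value and q-value of the authors, under headings as Cuffdiff writes them. The deposited log2 value is total RNA over SG RNA: 20565 of 20566 values matched the opposite of log2 (SG/total) within 0.01, and 537 other cells were damaged. All log2 folds given here are SG over total, recomputed from the FPKM columns. The authors' fold ratio in the yeast table was not used for tests. Of 25556 human rows, 16956 had been tested and 8600 not. In addition 26 gene names had been turned into dates, 23 rows had no gene name and 13 rows held several names. Human names were matched to GENCODE v29 for 23062 rows, for lengths and GC content only. The deposited human coordinates did not match that build (1052 starts lay within 5 kb), so coordinates are printed as deposited. Levels of Y-linked genes and XIST were left out.

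Yeast genes with a mean of at least 10 over the 6 libraries were tested with limma 3.58.1 (trend) on log2(value + 1), without a block, and called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on that log2(value + 1) scale, which mostly understates changes of low genes but can overstate them where a library is at 0, as for YMR316C-A (4.05 against 2.94 with edgeR). P values measure the spread between libraries. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The human group values cannot support a test, so the calls are the authors' at q under 0.05 among tested, named genes with a mean of at least 1 FPKM. Human lists are described by the percentile of their median log2 fold among 10000 random lists of the same size, matched in 20 bins of mean FPKM. Neither these random lists nor camera took gene length into account. Length and GC content were compared with log2 folds by Spearman rho, also within 5 bins of mean expression. Random-list percentiles and the limma procedure were tested on simulated data. Over the 6114 simulated yeast genes, 54.5% of 2-fold and 91.0% of 4-fold changes were recovered (log2 folds of 1 and 2), and 2.68% of calls were false. Only 99 and 100 genes were given these changes, and 4 calls were false. That is a far smaller share of changed genes than was called in the data, so these rates may not carry over. For U-2 OS lists of 40 genes, 5 of 100 unshifted lists and 50 of 50 lists shifted by 1 on the log2 scale fell outside the central 95% of random lists.

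The gene lists, the main tests, most alternatives and the rule for named genes were fixed before the data were examined. Tests and settings chosen later are marked as such in the closing sections. The rule took the 8 largest and 8 smallest log2 folds. In yeast these needed an adjusted p under 0.05, a mean of at least 50 and all 3 SG values on the same side of all 3 total values. In U-2 OS cells they needed q under 0.05 and a mean of at least 5 FPKM, without small structured RNAs, pseudogenes and clone names. The rule added the 5 most abundant in SG RNA, a panel of 8 genes per organism and up to 2 of the highest and 2 of the lowest members of each list. Other members of a list named in the text complete small counts and were chosen after their values were seen, as were the genes of the closing section. Alternatives covered pseudocounts, filters, scalings, the replicate block, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, leaving out each library, other FPKM minimums and other transcript choices. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom of their read counts was at least 78.0. Calculations used R 4.3.3, Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.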

Results

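The series measured which RNAs collect in stress granules (SGs), the RNA and protein assemblies that form in the cytoplasm when translation initiation is blocked. RNA of purified SG cores was sequenced beside total RNA in 12 libraries, 3 in each of 4 groups. The human libraries came from U-2 OS cells, an osteosarcoma line, that carried the SG protein G3BP1 fused to GFP and were exposed to 0.5 mM sodium arsenite for 60 min. The yeast libraries came from Saccharomyces cerevisiae of the BY4742 background, with the poly(A)-binding protein Pab1 fused to GFP, after 30 min in sodium azide. The U-2 OS cores were enriched by centrifugation steps and the yeast cores were taken from an SG-enriched fraction, and both were captured through GFP. The comparison asks which RNAs are over- or under-represented in SG cores relative to total RNA under the same stress. No libraries from unstressed cells or from a mock purification were analysed here. The yeast libraries held 36500472, 46055626 and 38033496 gene-assigned reads in SG RNA, and 46981071, 36639668 and 49568442 in total RNA. For U-2 OS cells 1 FPKM value per gene and group was available, so those values have no replicate spread and their depth is unknown.

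In azide-stressed yeast, the mRNA of the very long gene DYN1 was among the 8 largest increases in SG RNA, and those of the glycolytic genes PGK1 and GPM1, the elongation factor genes TEF1 and TEF2 and the ribosomal protein gene RPL25 were among the 8 largest decreases. DYN1, the dynein heavy chain (YKR054C, R64 chromosome XI, 535647 to 547925), rose from 13758 ± 4356 normalised reads in total RNA to 109372 ± 28927 in SG RNA (SD, n = 3 each; log2 fold 3.00 ± 0.27 SE, limma adjusted p = 2.84e-05). REA1, also called MDN1, an ATPase of ribosome assembly (YLR106C, chromosome XII, 349006 to 363738), rose from 38202 ± 15395 to 273665 ± 79026 (log2 fold 2.88). The cell wall protein genes FIG2 (YCR089W, chromosome III, 267434 to 272263) and DAN4 (YJR151C, chromosome X, 712255 to 715740) rose with log2 folds of 3.17 and 3.07. At the other end, PGK1, phosphoglycerate kinase (YCR012W, chromosome III, 137746 to 138996), fell from 263606 ± 52939 to 15159 ± 5791 (log2 fold -4.17 ± 0.31 SE, limma adjusted p = 2.13e-05). GPM1, phosphoglycerate mutase (YKL152C, chromosome XI, 163642 to 164385), fell by 4.16 on the log2 scale, and RPL25, a protein of the large ribosomal subunit (YOL127W, chromosome XV, 80348 to 81190), fell by 4.07.

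Of 6160 yeast genes tested, 1856 were higher and 1965 lower in SG RNA at a limma adjusted p under 0.05, and 994 and 1166 of them differed by at least 2-fold. The remaining 2339 did not pass the test. When each library was scaled to the same total instead, the median of all genes shifted by 0.39 on the log2 scale, 2538 genes were higher and 1268 lower, and the share of higher calls went from 48.6% to 66.7%. Directions below are therefore relative to the deposited scaling. The authors' deposited table called 916 genes enriched and 1106 depleted, of which 904 and 1102 were also at least 2-fold changed in the same direction here.

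Among the 8 genes with the largest increase were also some that are short, poorly characterised or absent from the annotation. The log2 fold was 4.05 for YMR316C-A, 3.79 for YIL082W, 3.48 for YER188C-A, 2.99 for YPR204W and 2.95 for YOR192C-C. YMR316C-A overlaps YMR316W on the opposite strand, YIL082W was not in the R64 annotation used here, and YPR204W belongs to a family repeated at chromosome ends, so their reads are uncertain. The YIL082W value also varied between SG libraries (1930 ± 1607 normalised reads, SD, n = 3), and its log2 fold was 3.14 without SG replicate 2. Without total replicate 2, where YMR316C-A was listed at 0, the log2 fold was 2.43 for YMR316C-A and 2.72 for YER188C-A. Without total replicate 3 it was 5.12 for YMR316C-A, and on whole reads it was 2.94 with edgeR and 2.97 with DESeq2. With a pseudocount of 8 it was 2.90 for YMR316C-A and 2.74 for YER188C-A. The 8 largest decreases also held TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene (log2 fold -3.82), the enolase gene ENO2 (log2 fold -3.79) and YBR191W-A (log2 fold -3.84), which was not in the annotation. The pair TEF1 and TEF2, which encode the same elongation factor and can share reads, had log2 folds of -3.76 and -3.73.

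The 5 yeast genes with the most reads in SG RNA were FAS1, FAS2, REA1, ACC1 and FKS1. These values are not divided by gene length, so the ranking favours long genes. FAS1, a fatty acid synthase subunit, stood at 438740 ± 59116 normalised reads in SG RNA against 262481 ± 3507 in total RNA (SD, n = 3 each; log2 fold 0.73, limma adjusted p = 0.0983). The log2 fold was 0.83 for FAS2 (limma adjusted p = 0.0405), 0.81 for ACC1, acetyl-CoA carboxylase (limma adjusted p = 0.0382), and 0.59 for FKS1, a glucan synthase subunit (limma adjusted p = 0.116). edgeR and DESeq2 on whole reads and the scaling to the same total also called FAS1 and FKS1 higher (FAS1 adjusted p = 0.0239 with edgeR, FKS1 adjusted p = 0.0493 with edgeR). The FAS2 call was lost without SG replicate 3 or any 1 of the total libraries (limma adjusted p of up to 0.132, without total replicate 1) and without a filter on low genes (0.117). The ACC1 call was lost without SG replicate 2, SG replicate 3 or any 1 of the total libraries (limma adjusted p of up to 0.127, without total replicate 1) and without that filter (0.0993). Of the genes fixed as a panel, PAB1, the mRNA of the tagged protein, was 44185 ± 2805 in SG RNA and 98926 ± 5342 in total RNA (log2 fold -1.16). The log2 fold was -3.40 for the glycolytic gene TDH3, -3.21 for RPL3, -1.62 for the disaggregase gene HSP104 and -1.51 for the proton pump gene PMA1.

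**Figure D1:**
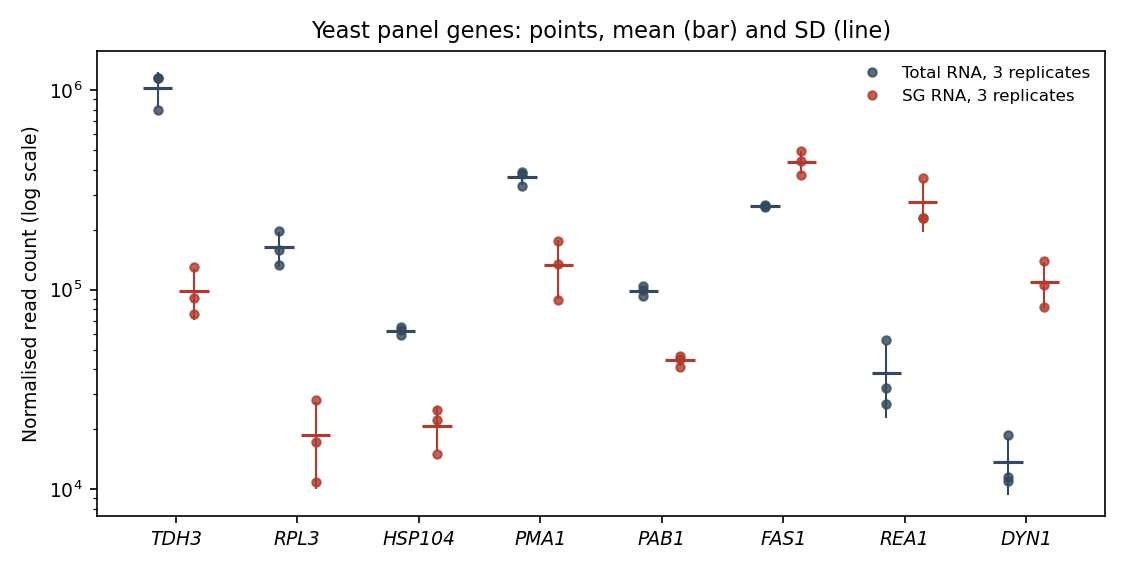
Normalised read counts (log scale) of 8 panel genes in the 3 total RNA (dark) and 3 SG RNA (red) libraries of yeast, with points for libraries, bars for means and lines for SDs. DYN1, REA1 and FAS1 lie higher in every SG library than in every total library (only FAS1 did not pass the limma test), and TDH3, RPL3, HSP104, PMA1 and PAB1 lie lower.

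Most yeast mRNAs of ribosomal proteins, glycolysis, the respiratory chain, the proteasome and histones were lower in SG RNA. Of 137 cytosolic ribosomal protein mRNAs, 136 fell, with a median log2 fold of -2.12, and RPS22B (log2 fold -0.06) did not pass the test. RPL10 fell by 3.62 on the log2 scale. RPL31B (log2 fold -0.47) lost its call without SG replicate 3 or any 1 of the total libraries (limma adjusted p of up to 0.158, without total replicate 2), after median centring, and when libraries were scaled to the same total. Of 21 glycolysis and fermentation mRNAs, 19 fell, with the lowest median of the 14 groups, -3.14. The other 2, PDC5 (log2 fold 0.17) and PYK2 (log2 fold 0.07), minor forms of pyruvate decarboxylase and pyruvate kinase, did not pass, and were called higher when libraries were scaled to the same total (limma adjusted p = 0.0192 and 0.0328). Of 40 respiratory chain and ATP synthase mRNAs 36 fell (median -1.34; COX13 -2.64, CYC1 -2.61), and none rose. Of 33 proteasome mRNAs 30 fell (median -1.07; PRE2 -2.19), while the mRNA of the proteasome transcription factor Rpn4 (RPN4) rose by 0.41, a call lost without SG replicate 3, total replicate 1 or total replicate 2 (limma adjusted p of up to 0.140). Of 10 histone mRNAs 9 fell (median -1.51; HHT1 -2.26). HTB2 (log2 fold -0.66) lost its call without SG replicate 3, total replicate 1 or total replicate 2 (limma adjusted p of up to 0.0718, without total replicate 2) and when libraries were scaled to the same total (log2 fold -0.26, limma adjusted p = 0.285). Adjusted over the list alone, these counts were the same except that 2 proteasome mRNAs were higher. The camera adjusted p at a preset correlation of 0.01 was 4.60e-27 for ribosomal proteins, 8.60e-08 for glycolysis, 5.05e-10 for the respiratory chain, 4.60e-08 for the proteasome and 0.000198 for histones. With an estimated correlation no call of these 5 lists held (adjusted p = 0.324 for each). With fry, which does not compare a list with other genes, the adjusted p lay between 0.000799 and 0.00205. Median coding lengths were 432 nt for ribosomal proteins, 451.5 nt for the respiratory chain, 399 nt for histones and 867 nt for the proteasome. Glycolysis had 1314 nt, and genes not called at least 2-fold changed had 1212 nt. Camera did not take length into account, so for the lists of short genes it does not separate length from group membership.

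Translation factors and chaperones were also mostly lower, with a few members on the other side. Of 40 translation initiation and elongation factor mRNAs 31 fell and 3 rose (median -1.16; camera adjusted p = 1.29e-05, adjusted p = 0.422 with an estimated correlation). The 3 that rose were GCD6 (log2 fold 0.91) and GCD1 (0.90), subunits of the guanine nucleotide exchange factor of initiation, and TIF4632 (0.65), a scaffold protein of the cap-binding complex. Of 39 heat shock and chaperone mRNAs 28 fell and 3 rose (median -1.21; camera adjusted p = 2.06e-05, adjusted p = 0.324 with an estimated correlation). The log2 fold was -3.53 for HSP12 (-2.87 without SG replicate 2) and -3.14 for the ribosome-bound chaperone mRNA ZUO1, while SSA3 rose by 1.87 and the mRNAs of the stress transcription factors HSF1 and MSN2 rose by 1.24 and 0.77. Of 44 cell wall and secretory protein mRNAs 30 fell and 1, TIR2, rose (median -0.95; camera adjusted p = 2.06e-05, adjusted p = 0.411 with an estimated correlation). The cell wall protein genes FIG2 and DAN4, which rose with log2 folds of 3.17 and 3.07, were not members of this list. Of 19 aminoacyl-tRNA synthetase mRNAs 13 fell and 2, ILS1 (log2 fold 0.84) and CDC60 (log2 fold 0.60), rose (median -1.20; camera adjusted p = 0.00264, adjusted p = 0.511 with an estimated correlation). The ILS1 call was lost without yeast total replicate 1 (limma adjusted p = 0.0537), and the CDC60 call without SG replicate 3 or any 1 of the total libraries (limma adjusted p of up to 0.0864, without total replicate 1). Adjusted over the list alone, the counts of these 4 lists were unchanged.

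The other yeast groups were higher, or had members on both sides. Of 81 mRNAs of very large proteins 70 rose and none fell (median 1.38; camera adjusted p = 6.12e-17, adjusted p = 0.350 with an estimated correlation). Their median coding length was 5112 nt, and camera did not take length into account. NEW1 (log2 fold -0.38) and YCF1 (-0.17) were the lowest and did not pass, although without SG replicate 2 NEW1 was called lower (limma adjusted p = 0.0226). Of 40 cell cycle regulator mRNAs 26 rose and 5 fell (median 0.67; camera adjusted p = 0.000447, adjusted p = 0.324 with an estimated correlation). The G1 cyclin CLN3 rose by 2.04, while the 5 lower ones were POL30 (log2 fold -2.35), RNR2 (-2.34) and RNR4 (-2.04), which serve DNA replication, and CDC28 (-1.02) and PCL1 (-0.61). The mRNAs of 44 SG and P-body proteins were split into 16 that rose and 16 that fell (median -0.00, camera adjusted p = 0.613). The median and the mean of this list, -0.02, lay below 0, while camera placed it above the other genes. WHI3 rose by 1.73 and PUF3 by 1.64, and the log2 fold was -2.76 for STM1 and -1.78 for PUB1. The median of this list was 0.39 when libraries were scaled to the same total. Of 79 ribosome biogenesis mRNAs 15 rose and 34 fell (median -0.38, camera adjusted p = 0.139), and this list passed without SG replicate 2 (camera adjusted p = 0.0227) or total replicate 1 (0.0357). That median was 0.02 when libraries were scaled to the same total. Of 42 plasma membrane transporter mRNAs 6 rose and 20 fell (median -0.48, camera adjusted p = 0.0555), a list that passed without SG replicate 3 (camera adjusted p = 0.00952), total replicate 1 (0.0343) or total replicate 2 (0.0359), and with the replicate block (0.0326). PDR12 rose by 1.55 and HXT2 fell by 1.83. Adjusted over the list alone, the counts were 71 higher for very large proteins, 27 higher and 5 lower for cell cycle regulators, and unchanged for the other lists. No members of the lists of mitochondrially encoded genes, small nuclear and nucleolar RNAs or Ty genes were found by name in the table used here. Entries outside the annotation, such as YIL082W, had no symbol to match, so it does not follow that such genes are absent.

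In arsenite-stressed U-2 OS cells, AHNAK was among the 8 largest increases in SG RNA, and mRNAs of histone and ribosomal protein genes were among the 8 largest decreases. AHNAK, which encodes a very large scaffold protein (chromosome 11, 62201015 to 62314332 as deposited, build not named), had 755 FPKM in SG RNA and 75.1 FPKM in total RNA, a log2 fold of 3.33. The other 7 largest increases were HIPK2 (log2 fold 3.25), MAP1A (3.23), BOD1L (3.20), SPEN (3.20), AHNAK2 (3.15), ANKRD11 (3.10) and CEP250 (3.09). The largest decreases were HIST1H4I (log2 fold -5.04), RPS29 (-4.86), HIST1H3H (-4.69), RPS21 (-4.51), HIST1H3B (-4.43), HIST1H2AD (-4.39), the mitochondrial protein gene ROMO1 (-4.23) and RPS12 (-4.23). RPS29 (chromosome 14, 50044038 to 50053094 as deposited) had 77.5 FPKM in SG RNA and 2254 FPKM in total RNA. Histone and ribosomal protein genes have near-identical copies, so the division of their reads is uncertain.

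The noncoding RNA NORAD, listed under its older identifier LOC647979 (chromosome 20, 34633539 to 34638882 as deposited), had 157 FPKM in SG RNA and 33.5 FPKM in total RNA (log2 fold 2.23). HUWE1, a ubiquitin ligase mRNA, had a log2 fold of 2.53, and DYNC1H1, the dynein heavy chain mRNA, had 96.7 FPKM in SG RNA and 17.1 FPKM in total RNA. GAPDH had 876 FPKM in SG RNA and 3422 FPKM in total RNA (log2 fold -1.97). ACTB had 1217 and 2464 FPKM (log2 fold -1.02), and the nuclear RNA MALAT1 12.7 and 64.4 FPKM (log2 fold -2.34). In the authors' deposited table each of these panel genes and each of the 16 named genes above had a q of 0.000113. That is the smallest in the table and was shared by 6796 of the 12371 tested, named genes with a mean of at least 1 FPKM. The mRNA of the tagged protein, G3BP1, had 271 FPKM in SG RNA and 244 in total RNA, with a q of 0.243 in the authors' deposited table. Leaving out small structured and mitochondrial RNAs, the most abundant SG RNAs were ACTB, THBS1 (1036 FPKM, log2 fold 1.46), MT2A (996 FPKM, log2 fold -0.53), HSP90AB1 (886 FPKM, log2 fold -0.00) and GAPDH. Of the genes named so far, ACTB, HUWE1, MALAT1, SPEN, ANKRD11, HIST1H4I, HIST1H2AD, ROMO1 and RPS12 share their deposited locus with another entry, so their FPKM values are uncertain. In the authors' deposited table HSP90AB1 had a q of 0.985.

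Of 12371 U-2 OS genes with a test and a mean of at least 1 FPKM, the authors' deposited table gave 4860 higher and 4203 lower in SG RNA at q under 0.05, and 3308 without a call. At least 2-fold changes among these calls numbered 2065 and 2003. Of the 12371 genes, 15 were listed at 0 in total RNA and 87 at 0 in SG RNA, and no fold was given for them. Over the whole table the authors' deposited table called 2457 genes enriched and 2791 depleted. The spread behind these q values cannot be recomputed from group values, and 29.3% of the genes shared a deposited locus with another entry. No scaling of the U-2 OS groups to the same total was tried, so directions are relative to the deposited FPKM values.

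Most U-2 OS mRNAs of ribosomal proteins, histones, the respiratory chain and the proteasome were lower in SG RNA. In the authors' deposited table all 81 cytosolic ribosomal protein mRNAs were lower (median log2 fold -2.38; RPL11 -0.64 the least), as were 40 of 41 replication-dependent histone mRNAs (median -3.18) and 77 of 79 respiratory chain and ATP synthase mRNAs (median -1.93; NDUFA4 -3.64). The authors' deposited table gave SDHA alone as higher in the last group (log2 fold 0.34). It also had 42 of 46 proteasome mRNAs lower (median -1.26), with PSMA7 at -2.65, and 4 higher, PSME4 (1.42), PSMD5 (0.82), PSMD2 (0.43) and PSMD1 (0.26). The medians of these 4 lists lay below all of 10000 random lists matched on mean FPKM (percentile 0 for each). Those random lists were not matched on length. Median transcripts were 1170 nt for ribosomal proteins, 509 nt for histones, 1268 nt for the respiratory chain and 1586 nt for the proteasome. The median over all genes with a length was 3350 nt, so length and group membership cannot be told apart by these percentiles. Glycolytic mRNAs had 13 of 17 lower and 2 higher in the authors' deposited table (median -0.59), which placed them at the 47.6th percentile. HK2 (log2 fold 1.08) and HK1 (0.87), the hexokinases, were the higher ones, and GAPDH and ENO1 (-1.52) were the lowest. Translation factors were divided, with 34 lower and 16 higher of 62 in the authors' deposited table (median -0.39, 50.5th percentile). EIF4G1 (1.78) and EEF1B2 (-2.62) were the extremes. PSME4, PSMD1, ENO1, EIF4G1 and EEF1B2 share their deposited locus with another entry, so their values are uncertain.

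Of the noncoding RNAs with a call, most were lower in U-2 OS SG RNA. Of the small structured RNAs with a finite fold the authors' deposited table had 60 lower, 1 higher (MIR4737, log2 fold 0.87) and 214 without a call (median -3.46, percentile 0). RN7SL1, the RNA of the signal recognition particle, had 3046 FPKM in SG RNA and 942963 FPKM in total RNA, and RN7SK had 3086 and 175015 FPKM. RMRP had 11152 and 128542 FPKM. The mitochondrial ribosomal RNAs RNR2 (21247 FPKM in SG RNA, 120422 FPKM in total RNA) and RNR1 (10323 and 19007 FPKM) were, with these 3, the 5 most abundant entries in SG RNA. Ribosomal RNA was removed before the libraries were made, so the RNR1 and RNR2 values may depend on that step. FPKM divides by transcript length, so values of RNAs near the fragment size are imprecise. Of 6 nuclear-retained long noncoding RNAs 5 were lower in the authors' deposited table (median -1.50, percentile 0.14), among them MALAT1, NEAT1 (-1.97), PVT1 (-1.62) and JPX (-1.38), and TUG1 was higher (1.56). Of 7 cytoplasmic long noncoding RNAs and snoRNA hosts, 6 were lower in the authors' deposited table, including SNHG8 (-2.81) and SNHG5 (-2.72), and NORAD alone was higher (list median -2.21, percentile 1.06). NEAT1, PVT1, JPX, SNHG8 and SNHG5 share their deposited locus with another entry, so their values are uncertain.

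Several other U-2 OS groups were higher, or had members on both sides. In the authors' deposited table all 60 mRNAs of very large proteins were higher (median 2.28), the least FLNC (0.74), and all 44 chromatin modifier mRNAs were higher (median 1.95), with MLL2 at 3.08 and NSD1 at 2.93. Both medians exceeded all 10000 random lists (percentile 100). These lists share members: 10 of the first and 6 of the second were in another list. Their median transcripts were 13362 nt and 8748.5 nt, against 3350 nt over all genes with a length. The random lists were not matched on length, so the percentiles here do not separate length from group membership. Of 383 zinc finger genes 259 were higher and 35 lower in the authors' deposited table (median 0.63, percentile 100), with ZNF107 at 2.90 and ZNF593 at -1.58. Of 40 spindle, kinetochore and centrosome mRNAs 29 were higher and 8 lower in the authors' deposited table (median 0.72, percentile 99.99), with CENPF at 2.52 and SPC24 at -1.48. Of 44 mRNAs of SG proteins 30 were higher and 4 lower in the authors' deposited table (median 0.57, percentile 99.99), with PRRC2B at 2.46 and LARP1 at 2.01. The lower ones were ZFAND1 (-1.42), EIF4A1 (-0.90), TIA1 (-0.88) and TIAL1 (-0.38). Stress-induced genes (median -0.29, percentile 73.8) had 13 higher and 21 lower of 44 in the authors' deposited table, EGR1 at 1.72 and HSPE1 at -2.05. Secreted and endoplasmic reticulum proteins (median 0.04, percentile 96.5) had 19 higher and 16 lower of 44 there, CYR61 at 1.95 and SEC61G at -3.28, with its median inside the central 95% of random lists and outside it when genes under 5 FPKM were left out (percentile 98.3). That median was -0.01 after centring on the median of all genes. Of 4 detected marker genes of other tissues KRT14 and TNNT2 were lower in the authors' deposited table and none was higher (median -0.50, percentile 12.8). The same uncertainty from a shared locus holds for MLL2, CENPF, PRRC2B, EIF4A1, EGR1 and HSPE1. No mitochondrially encoded mRNA was found by name. Adjusted over the list alone, the p values of the authors' deposited table gave 3 glycolytic mRNAs higher, 261 zinc finger mRNAs higher and 38 lower, 41 histone mRNAs lower, 48 small structured RNAs lower, and the same counts for the other lists.

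**Figure D2:**
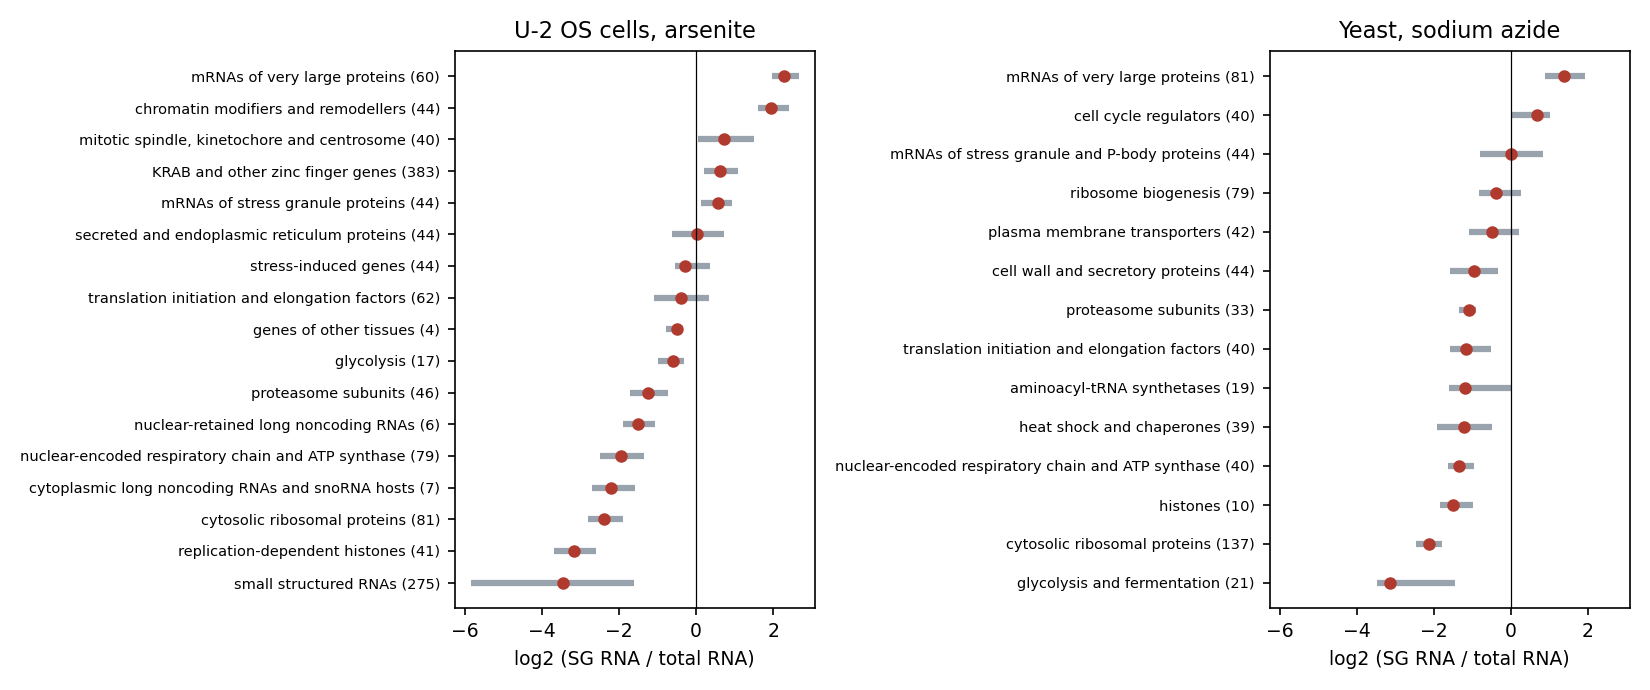
Median (point) and quartiles (bar) of the log2 ratio of SG RNA over total RNA for each gene list, with the number of members in parentheses, in U-2 OS cells (left, from group FPKM values) and yeast (right, from 3 against 3 libraries). Very large proteins stand highest in both (2.28 and 1.38), glycolysis stands at -0.59 in U-2 OS cells, and glycolysis and fermentation at -3.14 in yeast.

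RNA length tracked SG enrichment across genes in both organisms. In U-2 OS cells the Spearman rho between the log2 fold and the longest annotated transcript was 0.70 over 11712 genes, and with coding length it was 0.67. Genes at least 2-fold higher in SG RNA had a median transcript of 6420 nt, those at least 2-fold lower 1525 nt, and the rest 3287 nt. Over 5 bins of genes by length, the median log2 fold was -1.24 in the shortest bin and 1.04 in the longest. The 3′ untranslated region gave a rho of 0.44, the 5′ untranslated region 0.12 and GC content -0.11. Measured with the shortest annotated protein-coding transcript, rho was 0.16 for transcripts and 0.18 for coding length. Over the 1464 genes with a single annotated transcript length, a choice made after seeing the data, rho was 0.69.

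In yeast, rho with coding length was 0.48 over 5762 genes, and 0.38, 0.49 and 0.51 for SG replicates 1, 2 and 3 (SD 0.072, n = 3). Genes at least 2-fold higher had a median coding length of 2268 nt, those at least 2-fold lower 786 nt and the rest 1212 nt. The median log2 fold was -0.62 ± 0.22 in the shortest of 5 bins, -0.57 ± 0.087 in the next, and 0.91 ± 0.13 in the longest (SD over the 3 SG libraries). The Spearman correlation with GC content was -0.23 (SD 0.011, n = 3). The relation with length was steeper among abundant mRNAs. From the lowest to the highest of 5 bins of mean expression, rho with length went from 0.15 to 0.81 in yeast, and from 0.56 to 0.82 in U-2 OS cells. For GC content the same bins in yeast went from 0.07 to -0.62, and in U-2 OS cells all lay between -0.14 and -0.01. The Spearman correlation with mean FPKM was -0.10 in U-2 OS cells, and with the mean value in yeast it was -0.02. That yeast value is not divided by gene length and includes the SG libraries. Against abundance per kb in total replicate 1, with folds from total replicates 2 and 3, yeast rho was -0.57. For coding lengths under 1500 nt it was -0.60. Both values come from the abundance test of the closing section. All of these are relations across genes, which are not independent replicates, and no p was computed for them. There were 9 relations with log2 folds besides those with abundance per kb.

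**Figure D3:**
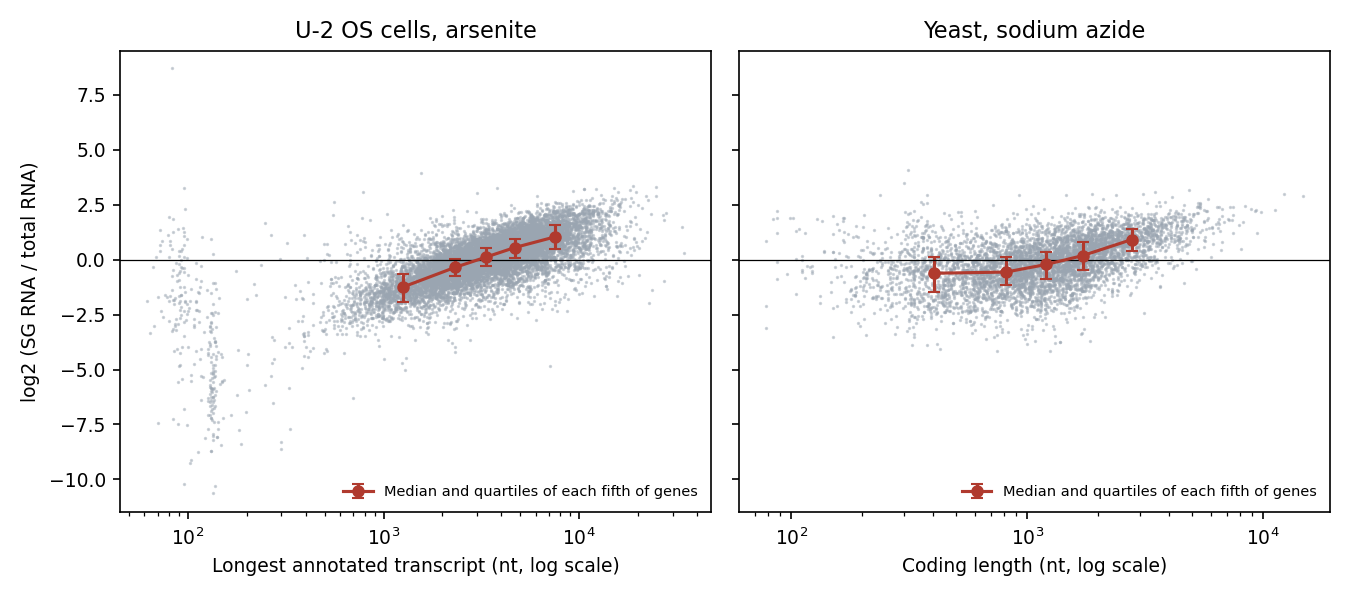
Log2 ratio of SG RNA over total RNA (grey points, genes) against the longest annotated transcript in U-2 OS cells (left) and coding length in yeast (right), both on log axes in nt, with the median and quartiles of each of 5 bins of genes in red. The medians go from -1.24 to 1.04 in U-2 OS cells and from -0.62 to 0.91 in yeast.

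The most abundant genes held a smaller share of SG RNA than of total RNA. In yeast the 100 most abundant genes held 23.7% ± 1.68 of normalised reads in SG RNA and 33.4% ± 2.26 in total RNA (SD, n = 3 each). Genes at least 2-fold higher in SG RNA made up 32.1% ± 3.36 of SG reads and 8.20% ± 1.59 of total reads. Those at least 2-fold lower made up 17.5% ± 3.29 and 55.5% ± 3.87. These genes were chosen on the same libraries, so their shares differ by construction. Levels in the 2 kinds of RNA still ranked alike, with a Spearman rho of 0.86 (SD 0.024, n = 3 SG libraries) across genes. In U-2 OS cells the 100 most abundant entries held 32.4% of summed FPKM in SG RNA and 90.2% in total RNA, where RN7SL1 dominated. Without small structured and mitochondrially encoded RNAs these shares were 16.3% and 32.2%. The Spearman correlation between SG and total FPKM was 0.79.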

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

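The test of coding length for glycolytic mRNAs and the comparison of lengths near chromosome ends were chosen after their results had been seen, and the other tests were chosen after the main comparisons and before their own results were seen. The human entries without a gene name entered no comparison of genes or gene lists above, but did enter the shares of all summed FPKM. They carried a signal in the authors' deposited table. Of 21 tested mitochondrial tRNA entries, 7 were higher in SG RNA and 2 lower at q under 0.05. Of the 7, 5 were listed at 0 FPKM in total RNA. Values of RNAs this short are imprecise, and no explanation was tested. TRNF had 619 FPKM in SG RNA and 99.6 FPKM in total RNA, while TRNS1 had 139 and 1121 FPKM. TRNY had 1336 and 465 FPKM but shares its deposited locus with TRNC, which had 184 and 298 FPKM, so its value is uncertain. With 3 libraries per group no single library was tested for standing apart.

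The rise of SG enrichment with RNA length was set against 3 technical explanations. If the short abundant mRNAs of ribosomal protein, respiratory chain, proteasome, histone and small or, in yeast, glycolytic genes alone produced it, it would vanish without them. Without these lists rho was 0.69 in U-2 OS cells (11194 genes left) and 0.46 (SD 0.075 over SG libraries, 5521 genes left) in yeast. Other short abundant mRNAs stayed in, and no rho with length given abundance per kb was computed in yeast. A part played by abundance is therefore not excluded. Loss of short transcripts from the libraries would leave little relation among long ones, but rho was 0.58 among human transcripts of at least 2000 nt and 0.47 (SD 0.032) among yeast genes of at least 1500 nt. The partial rho given GC content was 0.71 in U-2 OS cells and 0.45 (SD 0.076) in yeast, so GC content does not account for it either. A hypothesis is that long RNAs enter SGs more often, but faster sedimentation of long RNAs during purification may give the same relation and stays untested, since no mock or unstressed purification was analysed.

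Yeast genes within 25 kb of a chromosome end had a median log2 fold of 0.42 (SD 0.12 over SG libraries, 269 genes) against -0.07 for the other 5493, a difference that was not tested. Of the 269, 39.4% rose and 19.0% fell, against 30.7% and 34.3% of the others. Reads shared between repeated copies are a candidate explanation: genes near the ends with a standard name outside the repeated families stood only 0.15 (SD 0.067, 143 genes) above genes of like length. That set also leaves out genes without a standard name, not all of which are repeated. Coding length does not account for the pattern, since the 269 were shorter than the others (median 1128 against 1212 nt) and stood 0.46 (SD 0.094) above genes of like length, where length alone allowed at most 0.2 and 0.5 had been set to exclude it. Genomic DNA in the SG libraries stays open too, since the median excess per kb of the 106 genes that rose was 2.13 times the most that evenly spread DNA could add by the lowest genes elsewhere, between the bounds set for it. No biological explanation was tested.

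Yeast mRNAs of glycolysis and fermentation had a lower median log2 fold than ribosomal protein mRNAs (-3.14 against -2.12), with overlapping quartiles (-3.49 to -1.46 and -2.47 to -1.79) and no test of the difference. Coding length points the other way: 100% of the 21 were longer than the upper quartile of ribosomal protein genes (median coding lengths of 1314 and 432 nt). Abundance in total RNA may account for a part of the low folds. Against the 50 genes nearest in length alone, with folds from all libraries, the median difference was -2.62 (quartiles -3.45 and -1.85). Against the 50 nearest in length and abundance it was -0.93 (quartiles -1.30 and -0.35), with abundance from total replicate 1 and folds from total replicates 2 and 3. The value of -0.93 lies between the bounds set in advance, so abundance and a property of these mRNAs cannot be told apart here. Both comparisons were with genes outside the glycolysis list, not with ribosomal protein mRNAs alone.

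For the yeast comparison, only 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many genes called by limma, 3821, and the highest of the other splits gave 0. With 10 splits no share under 0.05 can be reached.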

How the results depend on the processing

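The single-transcript and shared-locus settings, and the yeast list values under TMM and same-total scaling, were chosen after seeing the data. No result changed sign past its threshold. Yeast counts stayed within 1.5 times except under scaling to the same total, which shifted every fold and gave 1268 genes lower, 1659 at least 2-fold higher and 719 at least 2-fold lower. edgeR called 1865 higher and 1907 lower, and DESeq2 1945 and 1962. With the replicate block 1929 were higher and 2076 lower. Samples of like number had deviation correlations of 0.035, 0.16 and 0.17, not all over 0.1, and each correlated best with its own number. Whether the numbers pair the samples stays unknown. The block gave the transporter list (median -0.48) a camera adjusted p of 0.0326 and changed no other list, and among named genes it added calls for RPN1, SIM1 and ZRT1. With an estimated correlation 11 list calls were lost. Their adjusted p was 0.324 for ribosomal proteins, respiratory chain, proteasome, glycolysis, heat shock, histones and cell cycle, 0.422 for translation factors, 0.350 for very large proteins, 0.411 for cell wall and 0.511 for tRNA synthetases. This setting differs from the preset one by construction. Leaving out single libraries, the transporter median ranged from -0.60 to -0.42 and the ribosome biogenesis median from -0.46 to -0.19, with some past the threshold.

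All 32 U-2 OS counts stayed within 1.5 times. None of their settings scaled the groups to the same total, the change that moved the yeast counts. The secretory list left the central 95% of random lists above 5 FPKM (median 0.0509). Above that minimum rho was 0.75 for transcript length, 0.71 for coding length and -0.14 for GC content. For genes with a single annotated transcript length these were 0.69, 0.63 and -0.0833, and with the shortest protein-coding transcript 0.16 and 0.18. The shortest annotated transcript has a median of 661 nt against 3350 nt for the longest. The cause of these shifts was not tested. Yeast rho with GC content was -0.25 above a mean of 50 and -0.20 without ribosomal proteins. By construction, the 50 most abundant genes held less: 28.0% and 88.4% in U-2 OS SG and total RNA, 16.9% and 25.5% in yeast. Without small structured and mitochondrial RNAs the U-2 OS shares were 16.3% and 32.2%. Of the yeast values for named genes, 36 lost a call, 22 gained 1 and 1199 stayed on their side of the threshold. Calls of single U-2 OS genes are the authors'. Apart from adjusting the authors' p values over each list alone, these calls were not recomputed under any setting. The shortest-transcript setting and the removal of small RNAs did not apply to the yeast table.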

Other observations

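The gene groups of the 2 organisms can be set side by side as values, without a test of the difference, since stress, organism, units and normalization differ. Ribosomal protein mRNAs had like medians, -2.38 in U-2 OS cells and -2.12 in yeast. The glycolysis list of U-2 OS cells stood at -0.59, and the yeast list, which also holds fermentation genes, at -3.14. The mRNAs of SG proteins stood at 0.57 in U-2 OS cells, and those of SG and P-body proteins at -0.00 in yeast.

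ZRT1, a zinc transporter gene (YGL255W, chromosome VII, 20978 to 22108), was high in both libraries numbered 1. It had 95804, 8928 and 6302 normalised reads in total RNA of replicates 1, 2 and 3, and 18942, 3094 and 3741 in SG RNA of replicates 1, 2 and 3. Its log2 fold of -1.54 did not pass the test (limma adjusted p = 0.202), but did with the replicate block (limma adjusted p = 0.000263). The log2 fold was -0.31 without total replicate 1 (limma adjusted p = 0.713), -2.37 without SG replicate 1 and -2.28 without total replicate 3.

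SG replicate 2 of yeast lay closer to total RNA than the others. Its Spearman rho across genes with the mean of the total libraries was 0.89, against 0.85 for replicate 1 and 0.84 for replicate 3. Without it 1965 genes were higher and 2112 lower.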
